A study of Pimephales promelas with 7 samples.

How the data were processed

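RNA from fathead minnow (Pimephales promelas, a small freshwater fish used in toxicology) was measured on 7 Agilent 2-colour arrays of 60-mer probes. Per the labels, 3 samples were solvent controls and 4 had been exposed to progesterone, and the series' design text calls them biological replicates. The labels do not say which samples came from the same fish. Each sample was labelled with Cy5 and hybridised against a mixed reference labelled with Cy3. No array had the dyes exchanged, so a dye effect of a single probe cannot be separated from a difference between sample and reference. It is shared by all 7 arrays and drops out of the comparison of progesterone with control. The labels disagree on the tissue. The protocols describe exposed ovaries and RNA taken from ovary, while the source and cell type fields say ovulated eggs.

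The deposited scanner tables hold spot intensities, which per the file headers were extracted with Agilent Feature Extraction version 9.5.1.1. The mean intensity of each spot and the median intensity of its surroundings are not normalized. The processed intensities in the same deposited tables were background-subtracted and dye-normalized by that software, per the file headers, and their log10 ratio is given beside them. The authors' deposited value table holds log2 ratios. Set against the log10 ratios of the same array it correlated at r = 0.999 on each of the 7 arrays, with slopes of 3.31, so its scale is log2 and its direction is sample over reference. Column means lay between 0.00135 and 0.00426, and column medians were 0.37, 0.34 and 0.38 for control 1, 2 and 3 and 0.40, 0.39, 0.39 and 0.38 for progesterone 1, 2, 3 and 4. It has values for 70.2% to 77.9% of the probe spots. How the authors centred and filtered it is not given in the sources used here.

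Here the mean intensities were background-corrected with normexp at an offset of 50, and the log2 ratio of sample to reference was normalized within each array by loess. The 1417 control spots and spots marked as outliers by the scanner software had weight 0 in the loess and were left out afterwards, and the 2 spots of each probe were averaged. Of 21495 probes, 14948 were well above background in the sample channel, on both spots, on at least 3 of the 7 arrays and were tested. The fit used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term) with Benjamini-Hochberg adjustment and a threshold of 0.05. The files give slides, and the slides were scanned separately. Slide 1 held controls 1 and 2 and progesterone samples 1 and 2, and slide 2 held control 3 and progesterone samples 3 and 4, so slide and treatment can be separated.

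Gene names were not obtained. Every probe's description in the scanner tables is Unknown. The probe names are 6937 accessions of expressed sequence tags (ESTs, single reads of cDNA clones) and 14558 assembled contigs, and 0 of them matched the 64593 genes of the gene table at hand. The 22 gene lists fixed before the data were examined, the tests on them and the genes that were to be given whatever the result were therefore not run. The rule for named items, also fixed then, took probes past the threshold with non-overlapping groups and, where too few passed, those of lowest unadjusted p with non-overlapping groups. It was applied to probe IDs instead of gene symbols, and 2 IDs per direction are given.

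Signal over background stood in for depth. The number of arrays limits the precision. The limma fit was tested on simulated data for the comparison of progesterone with control over the same 14948 probes, of which 200 were changed. When changes were added to the normalized log ratios of the real arrays, the fit recovered 0 of 50 probes changed 1.41-fold. It recovered 14 of 50 changed 2-fold, 33 of 50 changed 4-fold and 47 of 50 changed 8-fold, with 0 false calls. With independent noise it recovered 0, 21, 38 and 45 of 50 at those sizes, with 7 false calls. The changes entered after background correction and loess, so what these steps do to a change, as in dim probes, was not tested.

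Alternatives fixed before the data were examined were a normexp offset of 16, the scanner software's processed intensities, median centring, Aquantile between arrays, the authors' log2 table, 2 other filters on dim probes, slide as a block, replicate number as a block, each sample left out, array weights, an intensity trend, each channel alone and each slide alone. Principal components of the arrays as covariates, and the recount of sample against reference under other settings, were added after seeing the data.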

Results

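The study asked which transcripts accompany progesterone-induced germinal vesicle breakdown, the dissolution of the oocyte nucleus as meiosis resumes, in the fathead minnow ovary. Tissue was held for 4 h at 25 °C in medium with 500 ng/L progesterone (4 samples) or with 0.05% of the ethanol carrier (3 samples). The labels give no final ethanol level for the progesterone samples. The sample channel had a median signal over local background of 4.03 to 4.73 in the controls and 4.44 to 4.88 in the progesterone samples. Probes well above background made up 66.1% ± 2.97 (SD, n = 3) of the array in controls and 67.8% ± 4.71 (SD, n = 4) after progesterone, a difference within the spread between samples (exact permutation test, two-sided p = 0.571).

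No probe passed the threshold between progesterone and control with group as the only term. This fit took the 7 samples as independent. Each sample most resembled one of the other group, as given below. No fit used those pairs, and what they would do to the count was not tested. Log2 fold changes of the 14948 probes tested had a median of -0.01, and 95% of them lay between -0.37 and 0.33. The range was -1.38 to 1.31, and 9 probes exceeded a 2-fold difference in either direction. In limma with Benjamini-Hochberg adjustment 0 probes passed, the smallest adjusted p being 0.999999. At an unadjusted p under 0.05 there were 271 probes, 149 higher and 122 lower after progesterone, against 747.4 expected by chance. With the first 3 principal components of the arrays as covariates, added after seeing the data, 295 probes passed, 96 higher and 199 lower, and 3 of the 35 splits of the samples, the real one included, gave as many. The unadjusted count of the fit without covariates was 115 without control 1, 127 without control 2, 539 without control 3 and 496 without progesterone 1. The count and its split into higher and lower depended on the scaling. With the scanner software's processed intensities the count was 837, above the 747.4, split into 546 and 291. With the authors' log2 table it was 814 of 14841 probes, split into 570 and 244. Median centring gave 184, below the 747.4, split into 182 and 2, and moved the median of all probes to 0.19.

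**Figure D1:**
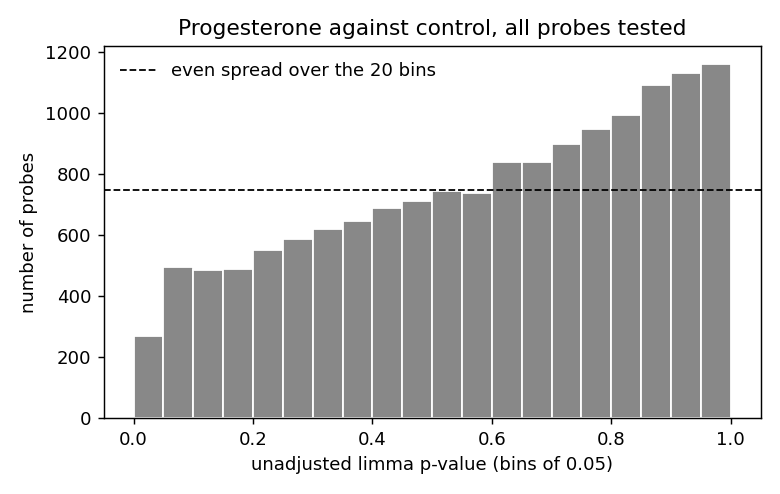
Number of probes (vertical axis) by unadjusted limma p-value in bins of 0.05 (horizontal axis) for progesterone against control; bars are counts of probes and the dashed line is an even spread of the 14948 probes. The lowest bin holds 271 probes, below the 747.4 of an even spread.

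The 2 probes with higher values and lowest p were EA_Pp_63388 and EA_Pp_68423, neither past the threshold. EA_Pp_63388, named after a contig, has the sequence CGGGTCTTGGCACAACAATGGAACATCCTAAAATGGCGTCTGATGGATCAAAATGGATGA. Its log2 ratio to the reference was -0.32 ± 0.19 (SD, n = 3) in controls and 0.37 ± 0.16 (SD, n = 4) after progesterone. That is a log2 fold change of 0.68 (SE 0.15), with a limma adjusted p of 0.999999 and an unadjusted p of 0.00205, and it was 1.04 with median centring. EA_Pp_68423, also named after a contig, has the sequence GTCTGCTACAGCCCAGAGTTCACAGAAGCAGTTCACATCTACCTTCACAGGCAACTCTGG. Its log2 ratio was -0.34 ± 0.22 (SD, n = 3) in controls and 0.42 ± 0.21 (SD, n = 4) after progesterone, a log2 fold change of 0.76 (SE 0.17), which was 0.45 within slide 2.

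The 2 probes with lower values and lowest p were EA_Pp_63410 and EA_Pp_53007, again not past the threshold. EA_Pp_63410, named after a contig, has the sequence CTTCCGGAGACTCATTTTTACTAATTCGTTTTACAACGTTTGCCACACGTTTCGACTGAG. Its log2 ratio was 0.58 ± 0.13 (SD, n = 3) in controls and 0.07 ± 0.05 (SD, n = 4) after progesterone, a log2 fold change of -0.51 (SE 0.11). The scanner software's processed intensities gave -1.09 and the authors' log2 table -1.11 for it. EA_Pp_63410 was the dimmest of the 4 named probes. Its mean log2 signal in the sample channel was 7.79, against 9.26 for EA_Pp_53007, 11.8 for EA_Pp_63388 and 14.6 for EA_Pp_68423. EA_Pp_53007, named after an EST, has the sequence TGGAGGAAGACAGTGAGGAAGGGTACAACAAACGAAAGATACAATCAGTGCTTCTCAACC. Its log2 ratio was 0.33 ± 0.11 (SD, n = 3) in controls and -0.31 ± 0.20 (SD, n = 4) after progesterone, a log2 fold change of -0.64 (SE 0.15). All 4 probes were chosen for having no overlap between the groups, and all were well above background on 7 of 7 arrays. In all, 563 probes (3.77%) had groups that did not overlap, where chance gives 5.71%.

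**Figure D2:**
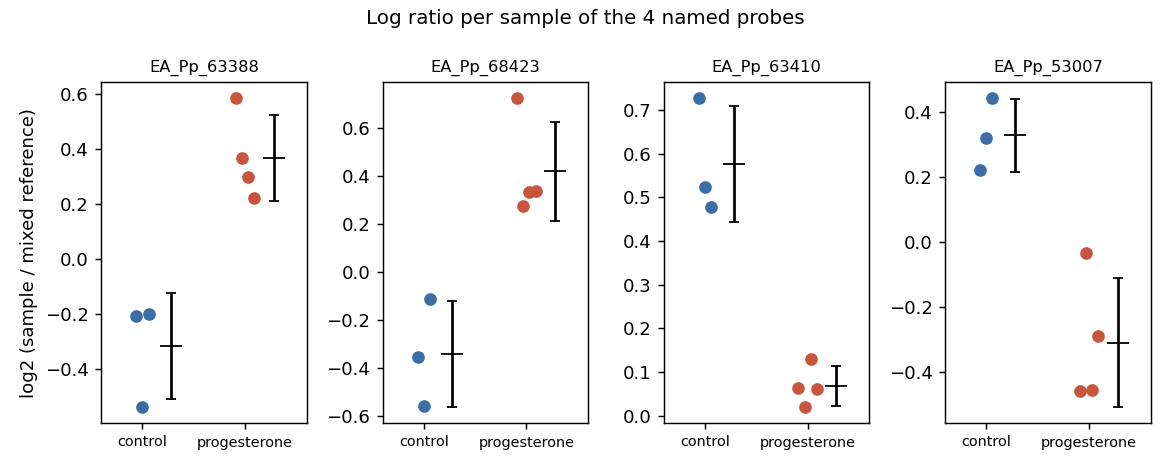
Log2 ratio of sample to mixed reference (vertical axes, which differ between panels) for 4 probes in 3 control (blue) and 4 progesterone (red) samples; each point is a sample and the black bars are the mean ± SD. EA_Pp_63388 and EA_Pp_68423 had higher and EA_Pp_63410 and EA_Pp_53007 lower log ratios in each progesterone sample than in any control, and none passed the adjusted threshold.

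With slide as a block 0 probes passed and 321 had an unadjusted p under 0.05, 156 higher and 165 lower. Within slide 1 (2 control and 2 progesterone samples) 0 probes passed and 185 had an unadjusted p under 0.05. Within slide 2 (1 control and 2 progesterone samples, the lone control assumed to vary like the others) the counts were 0 and 36. These fits rest on 4 and 3 samples, too few for their counts of 0 to bear on the call. The slide term itself, in limma with Benjamini-Hochberg adjustment, passed 0 probes, with 1396 at an unadjusted p under 0.05 against 747.4 expected by chance. That count was 773 without control 1, 487 without control 3, 550 without progesterone 4 and 2572 without progesterone 2.

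The SD among samples of a group had a median of 0.25 log2 units per probe, and that between the 2 spots of a probe 0.08. The median standard error of a fold change was 0.19, so the 95% interval reached 0.44 log2 units to either side at the median. For 12532 probes (83.8%) it lay within a 2-fold change. These intervals hold for each probe by itself and for this scaling. That of EA_Pp_63410 ran from -0.77 to -0.24, while the scanner software's processed intensities gave -1.09 for this probe. The intervals take the 7 samples as independent. Each sample most resembled one of the other group, and what this did to the intervals was not tested. Smaller changes, and changes of the remaining probes, were not excluded by these 7 arrays. Whether the intervals of the 12532 probes stay within 2-fold under other scalings was not tested, so 2-fold changes are not excluded for them either.

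The log ratios of different samples correlated at 0.851 to 0.990 across probes, which are not independent replicates. Each of the 7 samples had its highest correlation with a sample of the other group. The highest were 0.990 between control 3 and progesterone 4, 0.981 between control 1 and progesterone 2, and 0.961 between control 2 and progesterone 3.

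**Figure D3:**
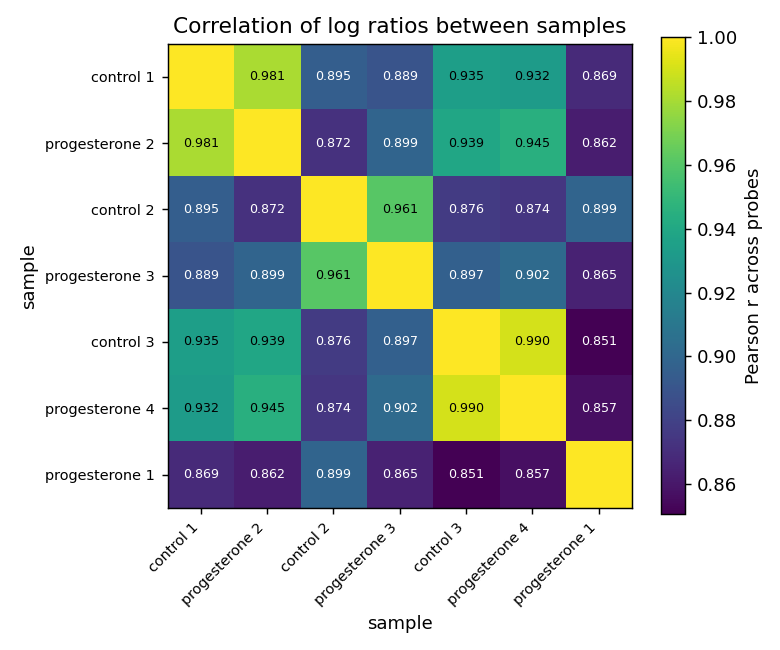
Pearson r of log2 ratios across 14948 probes between each pair of the 7 samples (both axes list the samples, placed so that close samples are adjacent; colour and printed values give r). The highest values, 0.990, 0.981 and 0.961, each join a control and a progesterone sample, and progesterone 1 reaches at most 0.899 with any other sample.

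Against the mixed reference, 12043 probes were well above background in both channels on all arrays. Of these, 504 were at least 4-fold below the reference on each of the 7 arrays and 0 were at least 4-fold above it. Median centring gave 202 below and 27 above. The lowest probe, EA_Pp_66378, had a mean log2 ratio of -9.13 ± 0.27 (SD, n = 7). The highest, EA_Pp_52564, had 5.20 ± 2.22 (SD, n = 7), with progesterone 1 at 0.27 and the others between 5.26 and 6.53. Both were singled out after their values were seen.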

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

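The tests of component 4 were all chosen after the result was seen. Among the 4 progesterone samples, 3 of the 20 measures examined held a sample far from the rest, judged by the gap to its nearest neighbour as a share of the range, and chance gives about 5% of such cases. For EA_Pp_68423 that share was 0.861, with progesterone 1 at a log2 ratio of 0.73 and the others between 0.28 and 0.34. For EA_Pp_52564 it was 0.893, with progesterone 1 at 0.27 and the others between 5.68 and 6.32. Over all tested probes, 1257 (8.41%) held such a sample, and it was progesterone 1 in 64.8% of them. This sample also had the lowest mean correlation with the other samples, 0.867 against 0.896 to 0.917.

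The third case was component 4 of the log ratios (6.31% of the variance), where the share was 0.943. Progesterone 4 scored -0.085 and the other progesterone samples between -0.385 and -0.368, while controls scored 0.217 to 0.577, so the component separated the groups (exact permutation p = 0.0286, two-sided). It did so under the 5 other normalizations too, of which Aquantile leaves ratios unchanged. The slides overlapped on it, with a gap of -0.585. Each slide held both groups, so any component that separated the groups had to give such an overlap, which decides nothing about the slide. Chance stays open: the p adjusted over 6 components was 0.171, but 0.0286 is the smallest p that 35 splits allow, so a single component that separates the groups could not have passed after adjustment. A difference in the share of probes above background stays open as well: its Pearson r with the scores was -0.158 (permutation p = 0.731) and Spearman's rho 0.0714 (permutation p = 0.906), but r was -0.714 without the 2 samples farthest from the median share, so it rests on few samples. An effect of progesterone on this component may exist and was not established.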

How the results depend on the processing

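Covariates from principal components, and the recounts against the reference, were chosen after seeing the data. The count of 0 called probes held under each setting fixed before the data were examined, but the zeros of the single-slide fits (too few samples), of the reference channel alone (not the sample channel) and of Aquantile show no stability. With 3 components as covariates, added later, 295 probes passed (96 higher, 199 lower); with 1 or 2 components 0 passed. The 4 named probes passed with 3 components, with fold changes of the direction given above. These 4 probes were chosen for having no overlap between the groups. Leaving out a sample, single-slide fits, the blocks, array weights, the intensity trend, the dim-probe filters and Aquantile therefore could not turn their direction. It could turn with the other normexp offset, processed intensities, the authors' log2 table, median centring, component covariates or either channel alone. It held under all of these except the reference channel alone. There all 4 lay near 0, EA_Pp_63388 at 0.08, EA_Pp_68423 at 0.08, EA_Pp_53007 at -0.05 and EA_Pp_63410 at 0.00883 (unadjusted limma p 0.161 to 0.915). The turned sign of EA_Pp_63410 has an SE of 0.08 and cannot be told from 0. That channel held the mixed reference on every array. At an unadjusted p under 0.05 the count ranged from 36 (within slide 2, which has fewer samples) to 837 (the scanner software's processed intensities) over the settings fixed beforehand; for the latter the cause was not tested. It was 553, 1093 and 3559 with 1, 2 and 3 components. Aquantile leaves ratios unchanged. The slide term passed 0 to 3 probes with each sample left out, 1 without control 2 and 3 without progesterone 3. Samples sharing a replicate number did not deviate together (r = -0.274, -0.709 and -0.274 from the group means), and none of the controls matched its own number best. With the replicate block 0 probes passed and 76 had an unadjusted p under 0.05. Gene-list tests and their alternatives were not run for want of gene names. Signal over background limits the 6547 probes not tested; without that filter 0 of 21495 passed and 529 had an unadjusted p under 0.05.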

Other observations

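The tests below were all chosen after the results were seen. Probes named after contigs were above background on all arrays in 70.1% of cases and those named after ESTs in 34.1%. In limma neither class held a called probe. At an unadjusted p under 0.05 there were 230 of the 11670 contig-named probes tested and 41 of the 3278 EST-named ones.

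A real count of 0 calls in limma is reached by all 35 splits of the 7 samples into 3 and 4 whatever the data, so it cannot be tested this way; the highest other split called 1137. Chance was not excluded for either of the other counts between the groups. For the 271 probes at an unadjusted p under 0.05, 24 of 35 splits reached as many, with 3863 the highest other. With 3 components as covariates, 3 of 35 splits reached the real 295, and the highest other was 1269. The third set progesterone 1, 2 and 3 against the rest, with 1180 calls, and differs from the treatment split only in the place of progesterone 4. Components 1 to 3 held 90.7% of the variance, and component 4, which separated the groups, 6.31%. Whether the 295 calls restate component 4 was not tested. In 20 simulated sets of independent noise, limma called 0 probes at most with 3 components and gave at most 894 at an unadjusted p under 0.05, against the real 3559, and without components the median was 766.5, against the real 271. Such noise leaves out the structure of the samples that the splits keep. In all 3 cases the highest other set control 2, progesterone 1 and progesterone 3 against the rest, which points to a structure of the samples.

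Samples resembled samples of the other group. Correlations of deviations from the mean differed by -0.242 within groups against between them (exact permutation, one-sided p = 0.914 for higher and 0.114 for lower values within groups). This was not beyond the spread over splits and restates the mixed pairs, so it decides nothing about treatment. The pairing depended on the measure, and correlation of log ratios was taken as the measure only after both had been examined. By log ratios the mutual pairs were control 1 with progesterone 2, control 2 with progesterone 3 and control 3 with progesterone 4, and the same pairs came out under the 5 other normalizations, of which Aquantile leaves ratios unchanged. By deviations, control 2 paired with progesterone 1 (r = 0.474) ahead of progesterone 3 (r = 0.416), and 0 pairs crossed the slides, against 1 by log ratios. An effect of the slide therefore stays open (mean difference 0.161, exact permutation, one-sided p = 0.2).

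A candidate explanation is a shared tissue source of the samples in a pair, which the labels do not state. The log-ratio pairs were first found over all 14948 probes, which include 69 with a gap above 2 log2 units between samples. Without those 69, r was 0.981 for control 1 with progesterone 2, 0.961 for control 2 with progesterone 3 and 0.990 for control 3 with progesterone 4. These pairs stayed together in all 69. Only 1 of the 105 ways to form 3 pairs, this one, did as well, and the next highest reached 48. The pairs and the measure were known beforehand, so this is not an independent check. The pairs by deviations stayed together in 42, which 5 of the 105 reached. None of the 69 probes separated the groups or the slides (0 and 0). That follows from the log-ratio pairs they kept together. Each pair held both groups, and control 2 and progesterone 3 lay on different slides. Any other cause that makes samples alike would give the same outcome, so the test does not single out a shared source, and no fit used these pairs.

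The excess of probes below the reference was weighed against 3 explanations. Normalization is argued against as the whole cause beyond 4-fold, where the lowest ratio of probes below to above over 6 settings was 7.48. Beyond 2-fold it may account for the excess, since median centring turned the ratio to 0.410. Transcripts scarce in the samples stay open. Above background in the reference on all arrays and in no sample were 538 probes, and 79 the reverse. None of these is among the 12043 probes of the excess, which were above background in both channels. Signal over background also differed, at 5.77 to 8.67 in the reference channel and 4.03 to 4.88 in the sample channel, so these counts do not decide. Probe-specific dye bias cannot be told apart from scarce transcripts, with 0 arrays of the opposite dye orientation.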
